A study of Mus musculus with 21 samples.

How the data were processed

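Gene expression was measured in liver RNA of 18 female NMRI mice on Affymetrix mouse arrays. The mice fell into 6 groups of 3, 1 group given SPC3372, an LNA-antimiR against microRNA-122, and 1 group given saline at each of 3 days (3, 9 and 23). The drug was dosed at 25 mg per kg on day 2. The labels name 2 array sets, p0617 with 15 arrays and p0621 with 6 arrays. All groups of day 3 and day 9 lie in p0617 and the comparison of day 23 lies in p0621, so each comparison of treated with control mice stays within 1 array set. The 3 treated mice of day 23, numbered 36, 37 and 38 in the labels, were also hybridised in p0617. Mouse numbers recur between groups killed on different days, and these groups were taken as different animals.

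The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and probe summary) per the submitters' processing notes. The RMA version and which arrays were normalized together are not given in the sources used here. The deposited values covered 45101 probe sets on each of 21 arrays, with array medians from 4.75 to 4.82 and single values from 2.15 to 14.98. RMA shrinks differences between dim probe sets, so folds of dim genes understate the change.

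Probe sets were named from the platform annotation. Of the 45101 probe sets, 64 were Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Entrez identifiers of 34741 probe sets were found in a RefSeq table of assembly GRCm38.p6, which updated 0 symbols. It was used for names only, as no build accompanies the deposited values. Each gene was represented by its probe set with the highest mean over the 18 arrays. That gave 18193 genes, of which 9010 had more than 1 probe set of their own.

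Group means of 18 arrays, 1 per mouse and p0621 for day 23, were fitted with limma (lmFit and eBayes), which gave 12 residual and 4.85 prior degrees of freedom. The 6 groups shared a single estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the 18193 genes with a threshold of 0.05, two-sided. Contrasts were treated minus control at each day, the mean of the 3 daily differences, the change in effect between days, and control day 9 minus control day 3. The 2 arrays of each treated mouse of day 23 were compared with the mouse as a block. Of 30 gene lists, each was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists within a contrast, beside camera with an estimated correlation and fry. The effects of 2 days were correlated across genes.

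The groups, tests, gene lists, other settings and the rule for naming genes were set before the data were examined. The rule takes the 10 largest increases and the 10 largest decreases of each day among genes past the threshold whose 3 treated arrays lie wholly above or below the 3 control arrays. It takes 5 each way for the mean of the days, 3 each way for a change in effect and up to 4 members per list. It always takes Aldoa, Bckdk, Cd320, Ndrg3, Slc7a1, Gys1, Ccng1, P4ha1, Tmed3 and Hjv (Hfe2 in older annotation). Means are given with the SD of 3 mice and differences with the SE of the fit.

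The other settings were a fit on a comparison's own arrays, quantile normalization or median centring of the arrays, filters at the median and at the 75th percentile of level, the mean of a gene's probe sets, every probe set, an intensity trend with a robust prior, the replicate number as a block, a change of at least 1.5-fold, all 21 arrays, the p0617 arrays of the treated day 23 mice, and leaving out each array in turn. The beta-actin control as a covariate and the omission of 2 arrays far from their group on it were added after the data were seen, as were, for the 2 array sets, a model without the mouse and a filter at the median level. The covariate was the log2 level of the 3' beta-actin probe set, and no setting adjusted for the 3' to 5' ratio. That level was 12.96, 13.12 and 13.09 in treated and 12.97, 12.71 and 12.74 in saline mice at days 3, 9 and 23. An adjustment for it can therefore also remove part of a drug effect. The search for microRNA-122 seed matches in 3' UTRs was not run, since it needs 3' UTR sequence. Lists were not retested under every alternative. The steps were tested on simulated data with known changes: at day 3, 43.3% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2 were recovered. For day 23 the shares were 53.7%, 92.5% and 100%. Unchanged genes gave 6 false calls at each of these 2 days. The simulated noise was independent between genes and alike on all days, so the shares do not tell how well real days compare. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.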

Results

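Liver gene expression was profiled after SPC3372, a locked nucleic acid oligonucleotide that binds microRNA-122, a microRNA made mainly by hepatocytes. NMRI mice, an outbred stock, received 25 mg per kg or saline on day 2, and livers were taken on days 3, 9 and 23 from 3 treated and 3 saline mice each. The 21 arrays came from 18 mice, because the 3 treated mice of day 23 were hybridised in both array sets. Over all probe sets, the 2 arrays of such a mouse correlated at 0.9934 to 0.9963 and different mice of a group at 0.9919 to 0.9949. The number of arrays limits the precision of every value.

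The 2 array sets were compared in the 3 treated mice of day 23. Aldoa, Bckdk, Ccng1 and Hjv differed between a mouse's 2 arrays by at most 0.26 in size on the log2 scale. Malat1, a nuclear long noncoding RNA, differed by -1.5 in mouse 36 (p0621 minus p0617), by -0.03 in mouse 37 and by 0.07 in mouse 38. In the same order Xist differed by -0.82, -0.01 and 0.38, and Meg3 by 0.18, 0.13 and 0.51. The p0621 array of mouse 36, which entered the day 23 fit, had a 3' to 5' log2 ratio of the beta-actin control of 1.33, against 1.09 in p0617. No gene passed the limma test of array set (0 of 18193, against 1864 at an unadjusted p under 0.05). The 1864 are a larger share than 0.05, and 2 arrays of each of 3 mice give little power for single genes. The test therefore does not show that the 2 sets agree. The SD of the log2 differences over genes was 0.143, beside 0.193 for the drug effect at day 23.

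At day 3 some of the genes that microRNA-122 is known to repress rose in treated liver and others did not pass the test. Bckdk, the kinase that inhibits branched-chain ketoacid dehydrogenase, reached 7.72 ± 0.11 against 6.57 ± 0.06 in saline mice (log2, SD, n = 3 each), a 2.22-fold rise (log2 1.15, SE 0.12, adjusted p = 2.38e-05). Aldoa, a glycolytic aldolase, rose 1.76-fold (log2 0.82, SE 0.08, adjusted p = 2.29e-05). Hjv, the hemojuvelin gene of iron regulation, rose 2.29-fold and Ccng1, cyclin G1, rose 1.95-fold. Ndrg3 rose 1.83-fold and Cers6, a ceramide synthase, rose 1.96-fold. Cd320, the transcobalamin receptor, differed by 0.37 (SE 0.10, adjusted p = 0.0503) and did not pass. Slc7a1, Gys1 and P4ha1 differed by 0.15, 0.10 and -0.12, and none passed. In the list of 27 targets from other studies 9 rose and 0 fell, with 12 and 0 adjusted over the list alone. The median change was 0.295 (camera adjusted p = 9.6e-11; 5.6e-12 to 0.000819 over its alternatives). In the list of 4 targets that the study itself measured, 3 rose (4 adjusted over the list alone, camera adjusted p = 1.56e-08; 2.19e-09 to 0.00367 over its alternatives). That list was chosen on these mice and is not independent evidence of its direction. It shares Aldoa and Ndrg3 with the first list, and of the other 25 genes there 7 rose.

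**Figure D1:**
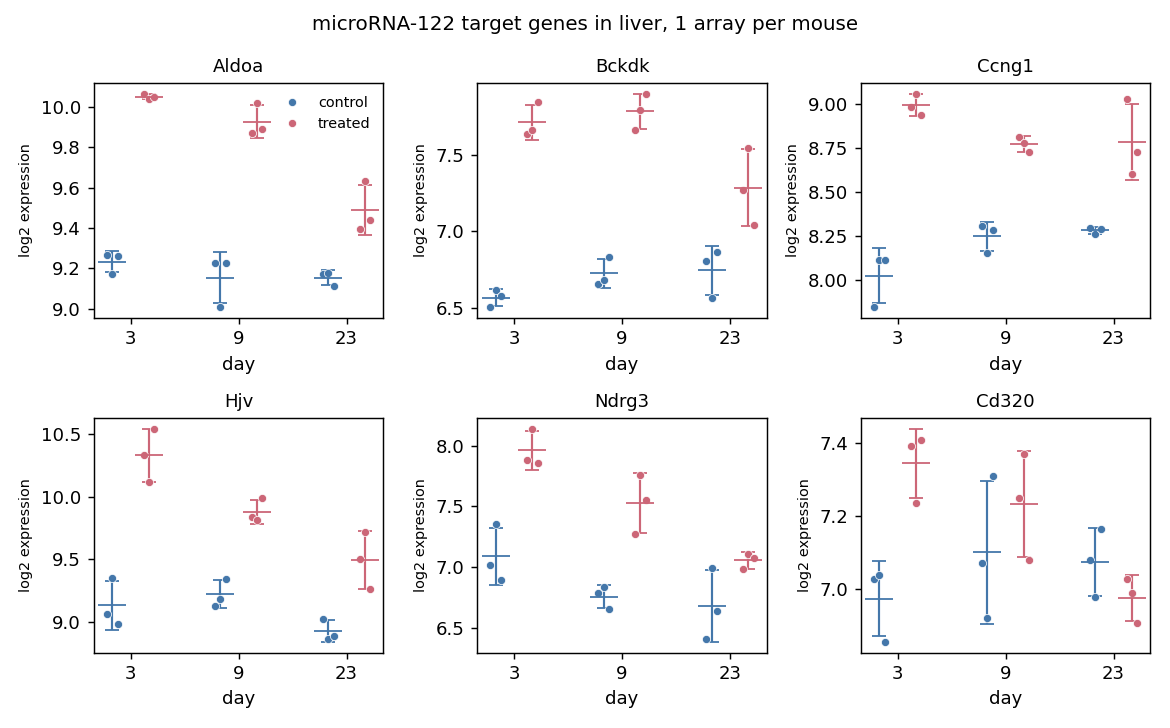
Log2 expression of 6 microRNA-122 target genes against day, with points for single mice, horizontal marks for group means and bars for the SD of 3 mice (saline blue, treated red). At day 3 Aldoa stands at 10.05 in treated and 9.23 in saline mice, and on that day the treated and saline mice do not overlap for any of the 6 genes, of which Cd320 did not pass the test.

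Most interferon response genes and some acute phase genes rose at day 3. Ifit1 rose 8.25-fold (log2 3.04, SE 0.37, adjusted p = 0.000101), Oasl2 7.68-fold and Irf7, an interferon regulatory factor, 6.52-fold. Of 27 measured interferon response genes 22 rose and 0 fell (26 and 0 adjusted over the list alone). Their median change was 0.902 (camera adjusted p = 1.71e-35; 4.1e-39 to 0.00878 over its alternatives). Saa2, a serum amyloid A gene of the acute phase, rose 28.5-fold from 8.74 ± 0.82 to 13.58 ± 0.07 (adjusted p = 4.43e-06). Saa3 rose 19.9-fold, Saa1 7.59-fold and Lcn2, lipocalin 2, 6.84-fold. In the acute phase list 5 of 25 genes rose (6 adjusted over the list alone). Its median change was 0.081 (camera adjusted p = 0.000732; adjusted p = 0.419 with an estimated correlation). Crp and the fibrinogen genes Fga, Fgb and Fgg differed by 0.04, -0.08, -0.07 and -0.05.

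Some markers of immune cells rose on the same day. Of 16 Kupffer cell and macrophage markers 10 rose (12 adjusted over the list alone), with a median change of 0.847. Marco, a scavenger receptor, rose 3.95-fold and Clec4f, a Kupffer cell lectin, 2.06-fold. The camera adjusted p was 2.42e-13, and adjusted p = 0.23 with an estimated correlation. Of 13 lymphocyte markers 3 rose (4 adjusted over the list alone, median 0.197, camera adjusted p = 0.000371; 7.63e-05 to 0.0118 over its alternatives). They were Ccl5, a chemokine (2.86-fold), and the granzymes Gzma and Gzmb (2.65-fold and 2.17-fold), while the T cell receptor genes Cd3e and Cd3d differed by 0.23 and 0.18. Gzmb lost its call without treated replicate 2 (adjusted p = 0.0581) or control replicate 2 (adjusted p = 0.0666), with a range from 0.00556 to 0.0666 over its alternatives. Of 28 cell cycle genes 3 rose (13 adjusted over the list alone, median 0.387, camera adjusted p = 2.12e-08; adjusted p = 0.284 with an estimated correlation). They were the replication factor Mcm5 (2.82-fold), the kinase Cdk1 (2.19-fold) and Top2a (2.22-fold), a dim gene whose call ended without treated replicate 1 (adjusted p = 0.0792) or treated replicate 2 (adjusted p = 0.0743; 0.00193 to 0.0792 over its alternatives). Among genes above the 75th percentile of level the cell cycle call ended, and the list mean of 0.511 became 0.261 (adjusted p = 0.219; 3.92e-12 to 0.284 over its alternatives). In these same arrays the 3' to 5' log2 ratio of the beta-actin control probe sets was 1.03 ± 0.02 in treated and 0.80 ± 0.05 in saline mice.

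**Figure D2:**
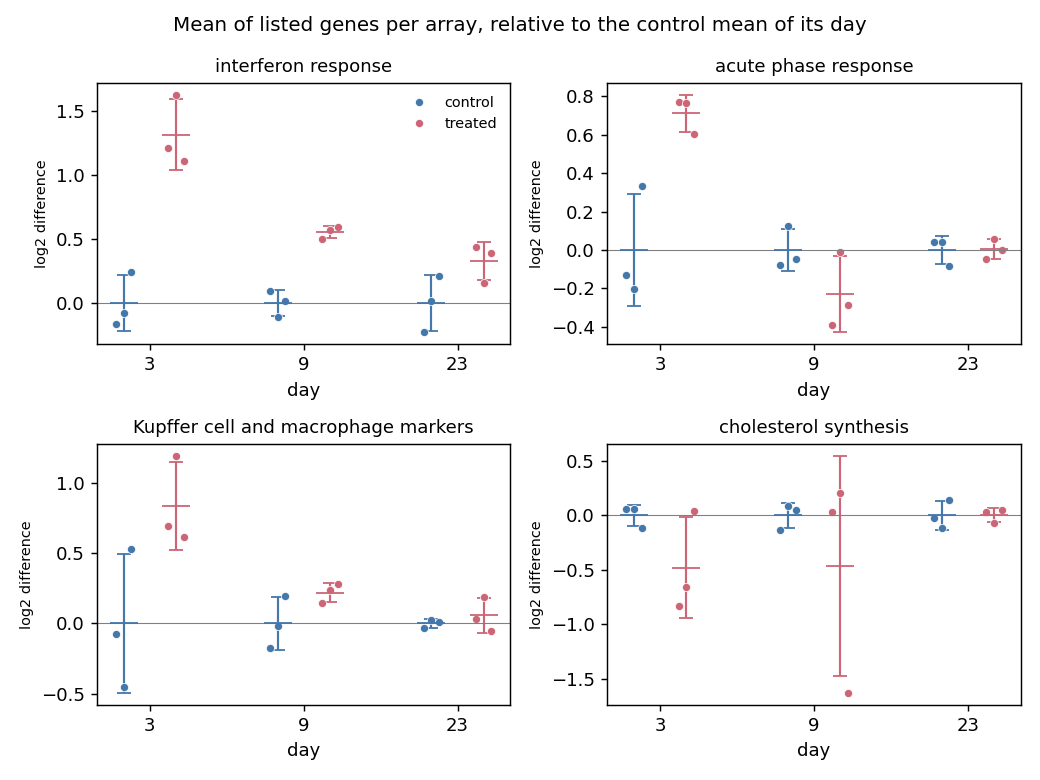
Mean log2 expression of the genes of 4 lists on each array, relative to the saline mean of the same day, against day (points, single mice; marks, group means; bars, SD of 3 mice; saline blue, treated red). The interferon list lies at 1.32 in treated mice of day 3, at 0.557 on day 9 and at 0.33 on day 23, and 1 treated mouse of day 9 lies at -1.63 for cholesterol synthesis.

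Rai14, an actin-binding ankyrin-repeat protein, fell most at day 3. It stood at 4.45 ± 0.13 in treated and 8.35 ± 0.15 in saline mice, a 15-fold fall (log2 -3.90, SE 0.16, adjusted p = 3.31e-10). The treated level lay below the median level of all probe sets, 4.78, where RMA compresses differences, so the fold can understate the difference. Of the other Rai14 probe sets above the median level, 1 fell by 1.65 (adjusted p = 1.48e-05 over every probe set) and 1 differed by -0.60 without passing (adjusted p = 0.44). The other large decreases were smaller and included the transporter Slc22a29 (2.77-fold lower), the zinc finger genes Zfp948 (2.16-fold) and Zfp51 (2.12-fold), and Ppp1r14b (2.00-fold). The camera test placed lipid synthesis lists lower, but 1 of 3 treated mice stood apart. In cholesterol synthesis the treated mice lay at -0.833, -0.653 and 0.043 relative to the saline mean, and in fatty acid and triglyceride synthesis at -0.575, -0.761 and 0.159 (replicates 1, 2 and 3). Of 17 cholesterol synthesis genes 0 rose and 0 fell by limma, also adjusted over the list alone (3 were lower at an unadjusted p under 0.05), and their median change was -0.452 (camera adjusted p = 0.000984; adjusted p = 0.644 with an estimated correlation). The mean of that list was -0.481, and it was -0.305 without treated replicate 1 and -0.743 without treated replicate 3. Of 25 fatty acid and triglyceride synthesis genes Srebf1, the lipogenic transcription factor, fell 1.76-fold (1 fell, 2 adjusted over the list alone, median -0.293, camera adjusted p = 0.00302; adjusted p = 0.612 with an estimated correlation). Its list call ended without treated replicate 2 (adjusted p = 0.21) or control replicate 2 (adjusted p = 0.118; 2.97e-08 to 0.612 over its alternatives). The mean of -0.393 became -0.208 and -0.254 there, and -0.668 without treated replicate 3. Of 20 unfolded protein response genes 1 fell, the disulfide isomerase Pdia6 (1 adjusted over the list alone, median -0.203, camera adjusted p = 0.00518; adjusted p = 0.428 with an estimated correlation). That list call ended without treated replicate 3 (adjusted p = 0.172; 9.6e-06 to 0.428 over its alternatives), where its mean of -0.217 became -0.109, and the mean was -0.353 without treated replicate 2. The calls of the cholesterol, fatty acid and unfolded protein lists also ended above the 75th percentile of level (adjusted p = 0.0855, 0.163 and 0.0667) and by fry (0.328, 0.311 and 0.115), with 2.19e-08 to 0.644 over the alternatives of the cholesterol list.

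In total 821 of 18193 genes passed at day 3, 479 higher and 342 lower. The count was 435 without treated replicate 1, 546 without control replicate 1 and 508 without control replicate 2, 253 in a fit on the day's own 6 arrays, and 311 for changes of at least 1.5-fold. Of the 59 named genes called at day 3, 42 kept the call without any 1 array. Treated replicates 1, 2 and 3 ended 14, 12 and 6 calls when left out, and control replicates 1, 2 and 3 ended 10, 14 and 8, with adjusted p up to 0.214. A fit on the day's own arrays ended 22, among them Clec4f (adjusted p = 0.0788; 0.000276 to 0.0788 over its alternatives), Cdk1 (0.0638; 9.87e-05 to 0.0638) and Gzma (0.0557; 0.00134 to 0.0557).

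At day 9 part of the target genes passed the test. Bckdk rose 2.09-fold (log2 1.06, SE 0.12, adjusted p = 0.000171), Aldoa 1.71-fold (adjusted p = 0.000133), Ndrg3 1.70-fold and Cers6 1.88-fold. Hjv rose 1.58-fold and Ccng1 1.44-fold. Tmed3, a cargo receptor of the secretory pathway, rose 1.60-fold (adjusted p = 0.0317; 0.0163 to 0.206 over its alternatives). Cd320 differed by 0.13. Of the 27 targets from other studies 8 rose and 0 fell (11 and 1 adjusted over the list alone, median 0.306, camera adjusted p = 1.3e-11; 4.55e-12 to 0.000513 over its alternatives). Of the 4 targets measured by the study 3 rose, also adjusted over the list alone (camera adjusted p = 1.8e-07; 4.02e-08 to 0.00617 over its alternatives), which again is not independent evidence.

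Gsn, the actin-severing protein gelsolin, rose 3.14-fold at day 9 (log2 1.65, SE 0.30, adjusted p = 0.00777), and Pcp4l1 and the splicing regulator Rbfox2 rose 3.13-fold each. The other Rbfox2 probe sets, all below the median level, differed by 0.14, 0.30 and -0.07 without passing. Apob, the structural apolipoprotein of very low density lipoprotein, rose 1.98-fold, and Abcg5, a sterol exporter, 1.57-fold. Pck1, a gluconeogenic enzyme, rose 1.68-fold, after 1.70-fold at day 3. Of 27 interferon response genes 8 rose (13 adjusted over the list alone, median 0.399, camera adjusted p = 4.86e-12; adjusted p = 0.256 with an estimated correlation). Ifi27l2a rose 2.66-fold and Oasl2 2.46-fold. Among 24 fatty acid oxidation and PPARA target genes 1 rose, Hadhb (2 adjusted over the list alone, median 0.193, camera adjusted p = 0.000775; adjusted p = 0.552 with an estimated correlation). The mean of that list, 0.222, was 0.111 without treated replicate 3, 0.353 without control replicate 2 and 0.143 without control replicate 3. Of 16 macrophage markers 0 passed the limma test, also adjusted over the list alone, and 6 had an unadjusted p under 0.05 (median 0.203, camera adjusted p = 0.0218; adjusted p = 0.721 with an estimated correlation), and of 15 stellate cell markers 2 rose, Reln and Dcn, also adjusted over the list alone (median 0.258, camera adjusted p = 0.0143; adjusted p = 0.594 with an estimated correlation). The beta-actin 3' to 5' log2 ratio was 1.14 ± 0.02 in treated and 0.93 ± 0.06 in saline mice.

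Decreases at day 9 included Got1, a glutamate transaminase, by 2.36-fold (log2 -1.24, SE 0.16, adjusted p = 0.000603), the complement gene C9 by 2.44-fold and the clock gene Arntl by 2.38-fold. Rai14 was 2.67-fold lower (adjusted p = 0.000217). Ranbp3l was 2.50-fold lower. Acacb, acetyl-CoA carboxylase 2, was 3.10-fold lower (adjusted p = 0.0383; 0.0211 to 0.175 over its alternatives). Of 25 fatty acid and triglyceride synthesis genes 1 fell (5 adjusted over the list alone, median -0.282, camera adjusted p = 0.0143; adjusted p = 0.705 with an estimated correlation). The 17 cholesterol synthesis genes had a median change of -0.37 with 0 genes past the limma test, also adjusted over the list alone, and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.00555; adjusted p = 0.705 with an estimated correlation). Without treated replicate 3 the mean of this list turned to 0.119 (adjusted p = 0.199; 9.46e-08 to 0.705 over its alternatives), from -0.463 with every array, and it was -0.712 without treated replicate 1 and -0.797 without treated replicate 2.

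At day 9, 511 genes passed, 348 higher and 163 lower. The count was 216 without treated replicate 1, 176 without treated replicate 3, 253 without control replicate 1 and 247 without control replicate 3. It was 132 on the day's own arrays, 287 with the beta-actin control as a covariate, 324 without 2 arrays far from their group on that control, and 191 at 1.5-fold. Of 63 named genes called at day 9, 21 kept the call without any 1 array. Treated replicates 1, 2 and 3 ended 28, 17 and 39 of these calls and control replicates 1, 2 and 3 ended 28, 24 and 30, with adjusted p up to 0.197. Hjv (0.0577) and Abcg5 (0.0572; 0.00396 to 0.0572 over its alternatives) were among those lost without treated replicate 3. Without treated replicate 3 the calls of the fatty acid synthesis, macrophage and stellate lists ended, each at an adjusted p of 0.0702. Without control replicate 2 the fatty acid synthesis list reached 0.0936 and the macrophage list 0.0521, and without control replicate 1 the macrophage list reached 0.272, with its mean at 0.13 in place of 0.219, and the stellate list 0.0873. The macrophage and stellate calls also ended above the median level (0.135 and 0.0863) and above the 75th percentile (0.241 and 0.103). The fatty acid synthesis call ended with the mean of probe sets (0.0821), and both it and the macrophage call ended with the beta-actin covariate (0.0644 and 0.107) and without the 2 arrays far from their group (0.0983 and 0.0569), where the fatty acid oxidation mean was 0.353 in place of 0.222. By fry the cholesterol, fatty acid synthesis, fatty acid oxidation, macrophage and stellate calls ended, at 0.136 to 0.46. Over all alternatives the adjusted p ranged from 0.00276 to 0.705 for fatty acid synthesis, 3.57e-06 to 0.552 for fatty acid oxidation, 0.00128 to 0.721 for macrophages and 0.00442 to 0.594 for stellate cells.

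At day 23 the list of genes past the test was led by a noncoding RNA. Meg3, a maternally expressed long noncoding RNA, rose 2.74-fold (log2 1.45, SE 0.27, adjusted p = 0.0338; 0.01 to 0.163 over its alternatives), with 8.87 ± 0.50 against 7.42 ± 0.12. Its log2 change ranged from 0.608 to 1.699 over those alternatives. Rdh9, a retinol dehydrogenase, rose 2.10-fold (adjusted p = 0.0168) and the transporter Slc35a4 1.58-fold (adjusted p = 0.0186). Ppm1m, a protein phosphatase, was 2.15-fold lower (log2 -1.11, SE 0.14, adjusted p = 0.00491). Cd207, a lectin known as langerin, was 2.01-fold lower (adjusted p = 0.0478). Among targets, Ccng1 rose 1.42-fold (adjusted p = 0.0423; 0.00459 to 0.173 over its alternatives). Bckdk (log2 0.54, adjusted p = 0.0509), Hjv (0.57, adjusted p = 0.0555), Aldoa (0.34, adjusted p = 0.0719) and Ndrg3 (0.38, adjusted p = 0.262) did not pass.

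Of the 27 targets from other studies 1 rose at day 23 (8 adjusted over the list alone, median 0.11, camera adjusted p = 2.68e-05; 4.04e-08 to 0.0186 over its alternatives). Of the 4 targets measured by the study 0 passed the limma test and 3 had an unadjusted p under 0.05 (3 rose adjusted over the list alone, median 0.356, camera adjusted p = 0.00611; adjusted p = 0.211 with an estimated correlation), and that list is not independent evidence. Of 27 interferon genes 0 passed limma's test and 11 had an unadjusted p under 0.05 (4 rose adjusted over the list alone, median 0.286, camera adjusted p = 2.75e-06; adjusted p = 0.45 with an estimated correlation), and the list mean of 0.33 was 0.218 without control replicate 1. Amino acid and urea metabolism genes, 19 with Bckdk among them, had a median change of 0.136 with 0 past the limma test and 4 at an unadjusted p under 0.05 (2 adjusted over the list alone, camera adjusted p = 0.000695; adjusted p = 0.45 with an estimated correlation). Cell cycle genes had a median change of 0.199 with 0 past limma's test, also adjusted over the list alone, and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0105; adjusted p = 0.721 with an estimated correlation). The cell cycle call ended without treated replicate 2 (0.114), control replicate 1 (0.288) or control replicate 2 (0.227), with a range from 2.18e-08 to 0.758 over its alternatives. Its mean of 0.205 was 0.119, 0.102 and 0.141 there, 0.374 without control replicate 3, and -0.094 above the 75th percentile of level, and its call also ended above the median level (0.154). By fry the interferon (0.294; 1.57e-12 to 0.45 over its alternatives), amino acid (0.154; 0.000154 to 0.45) and cell cycle (0.611) calls ended. With the p0617 arrays of the treated mice against the 6 p0617 saline mice of days 3 and 9, the amino acid mean of 0.15 became 0.084 (0.209), the interferon mean 0.583, the cell cycle mean 0.498 and the mean of targets from other studies 0.277 in place of 0.184. That setting mixes the drug effect with any difference between days. With the mean of probe sets the targets measured by the study had a mean of 0.185 in place of 0.289. The beta-actin 3' to 5' log2 ratio was 1.15 ± 0.16 in treated and 1.16 ± 0.04 in saline mice.

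The day 23 count was 70 genes, 34 higher and 36 lower, beside 2522 at an unadjusted p under 0.05. It was 22, 3 and 6 without treated replicates 1, 2 and 3, 5 without control replicate 2 and 13 without control replicate 3. Arrays of other days moved it as well, through the shared spread: 115 without treated day 3 replicate 2, 46 without treated day 9 replicate 1, 13 without control day 9 replicate 1 and 36 without control day 9 replicate 3. It was 0 on the day's own 6 arrays and 9 with the beta-actin covariate. It was 23 at 1.5-fold and 26 without the 2 arrays far from their group. It rose to 140 after quantile normalization (57 higher and 83 lower), 210 with an intensity trend, 214 above the median level, 387 above the 75th percentile and 137 with all 21 arrays. With the p0617 arrays of the treated mice it was 179, and 1587 when these were set against the 6 saline mice of days 3 and 9. The last count also holds differences between days, as saline mice of day 9 and day 3 alone differed in 1070 genes. Only Ppm1m among the 21 named genes called at day 23 kept its call without any 1 array. Treated replicates 1, 2 and 3 ended 14, 18 and 19 of the 21 calls and control replicates 1, 2 and 3 ended 10, 19 and 15, with adjusted p up to 0.138.

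Over the mean of the 3 daily differences, Bckdk rose 1.89-fold and Aldoa 1.56-fold (adjusted p = 5.71e-07 each), Hjv 1.75-fold and Ccng1 1.58-fold. The largest increases were Ifit1 (3.83-fold), Ifi27l2a (3.07-fold), the cytochrome P450 gene Cyp3a16 (3.01-fold), Oasl2 (3.00-fold) and Gbp6 (2.90-fold). The largest decreases were Hsd3b5 (4.04-fold), a hydroxysteroid dehydrogenase of male-typical liver, Cnmd (4.02-fold), Rai14 (3.69-fold), Ugt2b37 (2.78-fold) and Cyp39a1 (2.48-fold), an oxysterol hydroxylase. In all 2112 genes passed, 1019 higher and 1093 lower, of which 153 by at least 1.5-fold, and 1393 with the beta-actin covariate. Of the 27 targets from other studies 13 rose and 0 fell (17 adjusted over the list alone, camera adjusted p = 1.81e-13; 7.3e-14 to 0.000242 over its alternatives). Of 27 interferon genes 22 rose (24 adjusted over the list alone, camera adjusted p = 3.68e-27; 3.24e-29 to 0.0237 over its alternatives). Among 25 fatty acid synthesis genes 5 fell (2 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.00497; adjusted p = 0.597 with an estimated correlation). Of the 17 cholesterol synthesis genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.00679; adjusted p = 0.693 with an estimated correlation), and that call ended without treated day 9 replicate 3 (0.167; 2.32e-05 to 0.693 over its alternatives), with the list mean at -0.119 in place of -0.313. Of 16 macrophage markers 8 rose (14 adjusted over the list alone, camera adjusted p = 6.3e-08; adjusted p = 0.429 with an estimated correlation), and of 28 cell cycle genes 6 rose (9 adjusted over the list alone, camera adjusted p = 6.95e-06; adjusted p = 0.429 with an estimated correlation). Of 20 unfolded protein response genes 2 fell, also adjusted over the list alone, and of 15 stellate cell markers 0 rose and 1 fell (0 adjusted over the list alone) around a median of 0.184. Both these lists had a camera adjusted p of 0.0344 and adjusted p = 0.514 with an estimated correlation. The unfolded protein call ended when any 1 of 7 arrays was left out: treated replicates 1 (0.0601) and 3 (0.147) of day 3, treated replicates 1 (0.0534) and 3 (0.0635) and control replicate 3 (0.0532) of day 9, and control replicates 2 (0.0737) and 3 (0.0611) of day 23. The stellate call ended without treated day 3 replicate 1 (0.0771), treated day 9 replicate 3 (0.064), control day 9 replicate 1 (0.075), treated day 23 replicate 1 (0.0739) or control day 23 replicate 3 (0.143). On this mean, 8 list calls ended by fry (0.0531 to 0.279), 4 above the median level (0.0683 to 0.0868), 8 above the 75th percentile (0.0558 to 0.49) and 3 with the beta-actin covariate (0.0531 to 0.128). Over their alternatives the adjusted p ranged from 0.00181 to 0.514 for the unfolded protein list and from 0.00641 to 0.514 for the stellate list.

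Some genes passed on every day. Rdh9, Slc35a4, Ccng1, Gnpda1, Met, Ang and Rrm2b were among 14 genes higher at all 3 days, and Fuom, Ppp1r14b, Nop10, Timm9 and Timm8a1 among 7 lower at all 3 days. Days 3 and 9 shared 129 higher genes, where independent lists would share 9.16, and 39 lower genes (3.06), with 0 of opposite direction. Days 9 and 23 shared 20 higher (0.65) and 15 lower genes (0.323). The calls of different days rest on the same estimate of each gene's spread, so the figures for independent lists are no strict baseline. Log2 changes correlated across genes, which are not independent replicates, at r = 0.318 (rho 0.229) for days 3 and 9, 0.287 (0.255) for days 3 and 23, and 0.377 (0.279) for days 9 and 23. The groups of different days were taken as different animals, although some mouse numbers recur between them.

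**Figure D3:**
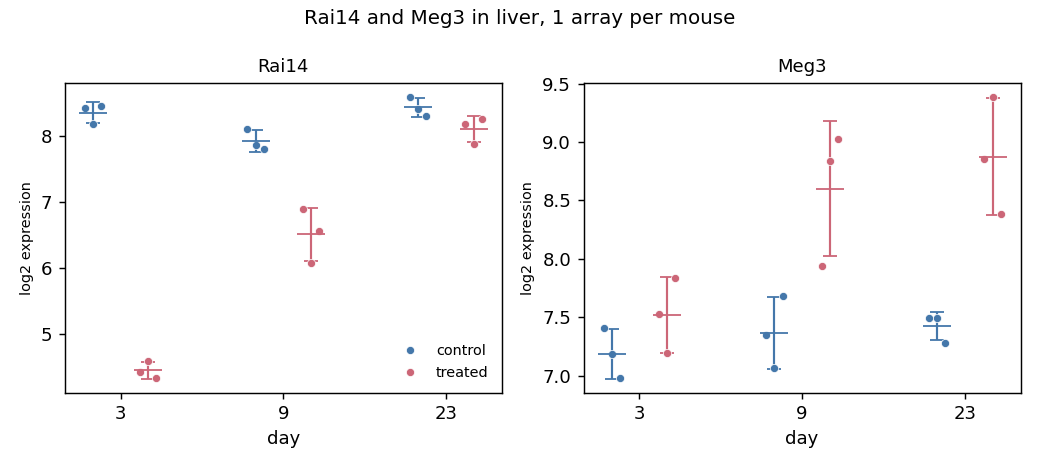
Log2 expression of Rai14 and Meg3 against day (points, single mice; marks, group means; bars, SD of 3 mice; saline blue, treated red). Rai14 in treated mice stands at 4.45 on day 3 and 6.51 on day 9, and Meg3 at 8.60 on day 9 and 8.87 on day 23.

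The change in effect between days was tested directly. The Rai14 difference shrank by 2.49 on the log2 scale from day 3 to day 9 (SE 0.23, adjusted p = 9.78e-05) and by 3.57 to day 23 (adjusted p = 3.74e-07), both from a treated day 3 level near background. Saa2 changed by -5.85 (adjusted p = 0.000173), Saa3 by -4.33 and Saa1 by -4.02 from day 3 to day 9. From day 3 to day 23 the interferon list changed by a mean of -0.985 (camera adjusted p = 8.41e-22; adjusted p = 0.0406 with an estimated correlation) and the targets from other studies by -0.177 (camera adjusted p = 0.00233; adjusted p = 0.0406 with an estimated correlation). Changes to day 23 cross from array set p0617 to p0621. An array set effect cancels there only if it shifts treated and saline mice alike. With the p0617 arrays of the treated mice against p0617 saline mice of days 3 and 9, the day 23 means were 0.583 for interferon and 0.277 for targets, in place of 0.33 and 0.184. Those saline mice were killed on other days, so drug and day cannot be told apart in these 2 means. Counts of genes were 26 for day 3 to day 9, 1 for day 9 to day 23 (Ranbp3l, 1.21, adjusted p = 0.0495) and 55 for day 3 to day 23. From day 3 to day 9 the count was 10 without treated day 3 replicate 1, 7, 14 and 49 without control day 3 replicates 1, 2 and 3, 13 and 11 without treated day 9 replicates 1 and 2, and 9, 64 and 9 without control day 9 replicates 1, 2 and 3. From day 3 to day 23 it was 36 without treated day 3 replicate 1, 24, 27 and 106 without control day 3 replicates 1, 2 and 3, 34 and 35 without treated day 23 replicates 2 and 3, and 28 without control day 23 replicate 3. The single gene of day 9 to day 23 became 0 without 1 of 14 arrays, 3 without treated day 9 replicate 2 and 4 without control day 9 replicate 2. On their own arrays the counts for day 3 to day 9 and day 9 to day 23 were 7 and 0.

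Saline mice of day 9 and day 3 also differed in expression. From day 3 to day 9 the clock-controlled transcription factor Dbp rose 37-fold (log2 5.21, SE 0.37, adjusted p = 1.44e-06) and the clock repressor Nr1d2 9.20-fold, while Cry1 was 7.01-fold lower. These genes were singled out after their values were seen. In all 1070 genes passed, 503 higher and 567 lower, and the count was 661 without control day 3 replicate 1, 705 without control day 3 replicate 3 and 608 without control day 9 replicate 3, and 693 on the day 3 and day 9 control arrays alone. Of 24 fatty acid oxidation genes 6 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.12e-06; adjusted p = 0.284 with an estimated correlation), and of 25 fatty acid synthesis genes 6 fell (7 adjusted over the list alone, camera adjusted p = 0.000375; adjusted p = 0.716 with an estimated correlation). Of 20 unfolded protein response genes 1 rose and 6 fell (2 and 9 adjusted over the list alone, camera adjusted p = 8.76e-05), of 15 stellate cell markers 2 fell (3 adjusted over the list alone, camera adjusted p = 5.9e-05) and of 21 bile acid genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0477). For each of these 3 lists adjusted p = 0.284 with an estimated correlation.

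The remaining 17 of the 30 lists were not called at any of the 3 days, with camera adjusted p from 0.0676 to 0.994. Among them, 2 of 21 bile acid genes rose at day 3, 3 at day 9 and 1 at day 23, and 3 of 17 lipoprotein genes rose at day 9. Of 14 glycolysis genes 2 rose and 1 fell at day 3, and 1 rose at day 9. Of 13 gluconeogenesis and glycogen genes 2 rose and 1 fell at day 3, and 2 rose at day 9. Of 23 xenobiotic metabolism genes 1 rose at day 3 and 2 at day 9, and of 15 p53 targets 2 rose at day 3, 1 at day 9 and 1 at day 23. Of 17 clock genes 1 rose at day 3, and 2 rose and 1 fell at day 9. Of 16 iron genes 1 rose at day 3, and 2 rose and 1 fell at day 9. Of 7 genes of sterol-regulated uptake 1 fell at day 3 and 1 at day 9. Of 13 sinusoidal endothelial markers 1 rose at day 3 and 1 at day 9, and of 8 cholangiocyte markers 1 rose at day 3. Of 5 adipose markers 1 fell at day 9. In the hepatocyte (12 genes), neutrophil (10), erythroid (5), pancreas (8) and fetal liver (9) lists 0 genes passed the limma test at any day, and at most 1 gene of each list had an unadjusted p under 0.05 on a day. On the mean of the days 3 of the 17 were called: xenobiotic metabolism (5 of 23 rose), p53 targets (4 of 15 rose and 1 fell) and sinusoidal endothelial markers (2 of 13 rose and 1 fell), each at a camera adjusted p of 0.0243 and adjusted p = 0.429 with an estimated correlation. The xenobiotic call ended without treated day 3 replicate 3 (0.0939), treated day 9 replicate 2 (0.121) or control day 9 replicate 1 (0.075), and the endothelial call without treated day 3 replicate 2 (0.0506) or control day 3 replicate 1 (0.0508). Over their alternatives the adjusted p ranged from 0.00543 to 0.429 for xenobiotic metabolism and from 0.00925 to 0.429 for the endothelial markers, and with the beta-actin covariate the xenobiotic mean was 0.046 in place of 0.077.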

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

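The tests of explanations for the interferon, acute phase and Rai14 results, the Malat1 value of mouse 36, the beta-actin covariate and the sorting of splits by whole days were chosen only after the result was seen.

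Effects that differed between days by a test of the difference itself drew attention. From day 3 to day 9 the effect changed in 26 genes, among them Rai14 (2.49), Rbfox2 (2.37), Nufip2 (1.32), Saa2 (-5.85), Saa3 (-4.33) and Saa1 (-4.02), and the lymphocyte markers changed by a mean of -0.531. From day 9 to day 23 it changed in 1 gene, Ranbp3l (1.21). From day 3 to day 23 it changed in 55 genes, among them Rai14 (3.57), Zfp51 (1.58), Gm15527 (1.49), Saa2 (-5.30), Saa3 (-4.15) and Saa1 (-3.32). Over the same span the interferon list changed by -0.985, the lymphocyte markers by -0.416, the targets from other studies by -0.177 and the targets measured by the study by -0.515. Changes to day 23 also cross from one array set to the other. In 100 drawn splits of the mice within days, the real one included, 7 gave at least 26 genes, 10 gave at least 1 and 11 gave at least 55, which taken alone does not exclude chance. These splits are no clean test of it, because a split that keeps a day's groups whole carries the drug effect of that day into the difference between days. The highest other splits gave 1547, 74 and 1357 genes, many times the real counts, which points to a structure of the samples: of the other splits as large, 6 of 6, 8 of 9 and 10 of 10 kept the real groups of 1 day whole. Splits that kept no day whole, singled out after the counts were seen, gave at most 0, 1 and 3 genes, so whether chance can be excluded is left open.

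For the mean of the days, 1 of 100 splits, the real one, gave as many as 2112 genes, a share under 0.05 that argues against chance. The highest other split gave 515 genes and was 1 of 25 that kept the real groups of at least 1 day whole. Splits that kept no day whole gave at most 1 gene. For single days the 10 splits of 6 mice are too few for a share under 0.05. The real values were 821, 511 and 70 genes at days 3, 9 and 23 and the highest other split gave 0 each time, so that 1 split, the real one, gave as many. For control day 9 minus control day 3 the 10 splits are again too few, with 1070 genes in the real split and 3 in the highest other. For the 2 array sets, 4 of 4 swaps of arrays within mice gave as many genes as the real 0 by limma (1864 at an unadjusted p under 0.05), with 0 as the highest other. Every swap gives at least 0 genes, so this count cannot decide the question, and 4 swaps are also too few for a share under 0.05.

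Probe sets without a single gene of their own, 10092 in number, lay outside the comparisons and also differed from saline. At days 3, 9 and 23, 108, 100 and 7 of them passed the threshold. Among them, 1 probe set with no gene named here was higher by 3.19, 3.65 and 2.03 on the log2 scale (SE 0.20, adjusted p = 1.07e-07, 3.62e-08 and 0.000368). Its means were 6.32 ± 0.17 against 3.13 ± 0.23 at day 3, 6.87 ± 0.02 against 3.22 ± 0.47 at day 9 and 5.37 ± 0.23 against 3.34 ± 0.29 at day 23 (SD, n = 3 each).

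At day 3, 22 of 27 interferon genes and 5 of 25 acute phase genes rose. A different hour of killing would move clock genes, and 1 of 17 passed, which argues against it. A single mouse is argued against too, since at least 16 interferon genes passed without any 1 of the 6 mice. A larger share of immune cells in the piece of liver stays open: the highest median of the 3 immune cell lists was 0.94 of the interferon median, so a change of cells and a change of expression within cells cannot be told apart. A response of the liver to the oligonucleotide is a further hypothesis, which no group given a different oligonucleotide tested here.

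Rai14 was lower at day 3. A single faulty probe set is argued against, since 1 other Rai14 probe set above the median level passed in the same direction, although a further one did not. The stellate and endothelial markers had a median change of 0.09, which argues against a loss of those cells. Poorer RNA in treated arrays is left open. The beta-actin 3' to 5' log2 ratio differed by 0.22, and the groups did not overlap. Treated arrays lay at 1.01, 1.05 and 1.01 and saline arrays at 0.81, 0.85 and 0.76. How far such a difference in RNA moves the Rai14 change of -3.90 was not tested. A direct or indirect effect of the antimiR on Rai14 may underlie the fall and remains a hypothesis, found and tested on the same mice.

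Malat1, Xist and Scaf11, singled out after their values were seen, differed at day 23 by 1.56 (SE 0.52, adjusted p = 0.174), 1.41 (SE 0.35, adjusted p = 0.0737) and 1.39 (SE 0.32, adjusted p = 0.0555), none past the test. In the same order they differed by -0.25, 0.08 and -0.24 at day 3 and by 1.30, 1.05 and 0.83 at day 9, none past it either. With the beta-actin control as a covariate the day 9 differences were 0.22, 0.36 and 0.20. Malat1 differed by -1.5 between the 2 arrays of mouse 36, a difference within 1 animal that points to a technical shift for that mouse. Beyond it, slopes on the beta-actin control within day 3 and day 9 groups correlated with the day 23 change at r = 0.06 across 11694 genes, which are not independent replicates, with 0.01 to 0.11 when 1 array was left out. The rule set before the test took r under 0.1 as against such a shift, and the r of all arrays met it. The range without 1 array, which the rule did not mention, crosses 0.1, so the shift is left open. At day 23, with that control as a covariate, the alternative run for these 3 genes, Malat1 stood at 0.65 (SE 0.14, adjusted p = 0.0716) and Xist at 0.82 (SE 0.15, adjusted p = 0.0625), while Scaf11 passed at 0.85 (SE 0.12, adjusted p = 0.0331). Meg3 stood at 1.5 (SE 0.30) against 1.45 (SE 0.27), and its call ended (adjusted p = 0.0716; 0.01 to 0.163 over its alternatives) with a like size and a larger SE.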

How the results depend on the processing

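The settings built on the beta-actin control, and for the 2 array sets a model without the mouse and a filter at the median level, were chosen only after the data were seen, and the other settings were fixed earlier. Outside the omission of single arrays, named genes kept direction and call in 1514 cases, lost the call in 350 and turned direction in 2, and list results did so in 463, 132 and 2. With 1 array omitted the counts were 2094, 480 and 0 for genes and 991, 69 and 2 for lists. The cause of a change was not tested unless stated. A search for microRNA-122 seed matches and a pseudocount were not run. Lists were not retested with the intensity trend, all 21 arrays, own arrays, every probe set or the fold limit, and between control days they were tested only with camera at both correlations and fry. Dim probe sets lie near background, where RMA compresses differences, which limits genes below the median level of 4.78, such as Top2a, and genes with 1 group below it, such as Rai14.

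Counts of genes fell on a comparison's own arrays, which leave fewer arrays to estimate the spread: 253, 132 and 0 at days 3, 9 and 23, 7 and 0 for the changes from day 3 to day 9 and from day 9 to day 23, and 693 between control days. At 1.5-fold or more they were 311, 191, 23, 153 for the mean of the days and 473 between control days. With the beta-actin covariate they were 287 at day 9 (79.1% higher, against 68.1%), 9 at day 23, 1393 for the mean (58.4% higher, against 48.2%), and 14 and 0 for the first 2 changes in effect. Without the 2 arrays far from their group they were 324, 26, 42, 5 and, between control days, 678. At day 23 the count was 140 after quantile normalization (40.7% higher, against 48.6%), 214 above the median level, 387 above the 75th percentile, 210 with an intensity trend and 137 with all 21 arrays, which gave 41 for day 3 to day 9. It was 179 for p0617 treated arrays against p0621 controls and 1587 against the 6 p0617 controls of other days, where drug and day are mixed. There Hectd2os turned to -0.351 and Colec12 to -0.198. The change from day 9 to day 23 had 0 genes by limma after median centring, above the 75th percentile and with the mean of probe sets (1581 at an unadjusted p under 0.05 in the reported fit).

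With the replicate number as a block the counts were 547, 216 and 0 at days 3, 9 and 23, 6, 0 and 29 for the changes in effect, and 453 between control days. The numbers do not pair the mice: 0 of 9 same-numbered pairs had deviations that correlated over 0.1 (-0.22 to 0.1), and 4 of 9 treated arrays correlated best with their own number.

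Correlations of effects between days 3 and 9, 3 and 23, and 9 and 23 were 0.371, 0.327 and 0.439 above the median level and 0.447, 0.38 and 0.495 above the 75th percentile. With every probe set the first 2 were 0.237 and 0.183, and with the mean of probe sets the middle one was 0.266. With the covariate they were 0.29, 0.264 and 0.426, and without the 2 arrays the last 2 were 0.265 and 0.327. Lists called with an estimated correlation numbered 4, 2, 1 and 3 at days 3, 9, 23 and their mean, and 1, 0 and 4 for the changes in effect. With fry they were 3 at day 9, 3 at day 23, 5 for the mean, and 3, 1 and 4 for the changes. Above the 75th percentile they were 6 at day 3, 4 for the mean, 4 for day 3 to day 9 and 5 for day 3 to day 23. The mean of probe sets gave 8 at day 23, and omission of the 2 arrays gave 3 for day 9 to day 23. Above the 75th percentile the mean of the cell cycle list turned from 0.205 to -0.094 at day 23, and its change from day 3 to day 9 turned from -0.408 to 0.249.

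When single arrays were left out, counts ranged from 435 to 876 at day 3, 176 to 529 at day 9, 3 to 115 at day 23, 1726 to 2192 for the mean, 7 to 64, 0 to 4 and 24 to 106 for the changes in effect, and 608 to 1123 between control days. Correlations ranged from 0.244 to 0.343, 0.244 to 0.299 and 0.316 to 0.393. Lists called for day 9 to day 23 ranged from 2 to 9, with 2 without treated day 9 replicate 3. Without that array cholesterol synthesis turned to 0.119 at day 9 (lowest -0.797 without treated day 9 replicate 2), and its change from day 9 to day 23 turned to -0.113 (highest 0.803).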

Other observations

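The test of the Dlk1-Dio3 region was set up before its result was seen, and the tests of clock genes and of sex-biased genes were chosen only after the result was seen.

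Meg3 lies in the imprinted Dlk1-Dio3 region with Rian and Mirg, noncoding RNAs of the maternal allele, and Dlk1, expressed from the paternal one. Of Rian and Mirg, 1 passed at day 9 or day 23: Mirg rose by 0.37 at day 9 (SE 0.08, adjusted p = 0.0213), while Rian differed by 0.73 at day 23 (SE 0.20, adjusted p = 0.104). On the mean of the days Rian rose by 0.44 (adjusted p = 0.0207) and Mirg by 0.20 (adjusted p = 0.00867), and Dlk1 differed by -0.09 (adjusted p = 0.532). A rise of the maternal noncoding RNAs of the region as a whole is a hypothesis that this test leaves open.

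Hsd3b5 fell on the mean of the days, and a shift toward a female-biased liver profile was tested as a hypothesis in these female mice. Of 11 male-biased genes 0 rose and 2 fell, Hsd3b5 (-2.02) and Ugt2b38 (-0.45), with a median of -0.13 (camera adjusted p = 0.0581). Of 11 female-biased genes 2 rose, Cyp3a16 (1.59) and Acot3 (0.61), with a median of 0.21 (camera adjusted p = 0.0248). For both lists adjusted p = 0.217 with an estimated correlation. The test asked for a camera adjusted p under 0.05 in both lists, and the male-biased list missed it, so the hypothesis was not borne out. Hsd3b5 prompted the test and Cyp3a16 was already among the largest increases on this mean, so neither is independent evidence.

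Clock genes differed between saline mice of day 9 and day 3, and a different hour of killing on those days may account for it. Of 11 clock genes not counted as seen before the test, 8 (72.7%) lay on the side that such a shift sets, and with the 4 genes seen earlier 12 of 15 (80%) did. Arntl and Per2 are among these 11, although their values had already been tabulated with the named genes. All 5 early-peaking genes fell, while of 10 late-peaking genes 5 rose and Per2 fell, against that side (-1.47, SE 0.27, adjusted p = 0.00328). Bhlhe41 (0.14, adjusted p = 0.529) and Usp2 (0.08, adjusted p = 0.895) were counted on that side and Hlf and Per1 (-0.02 each) against it, and none of these 4 passed. The first share fell short of the 80% that the test asked for, so the hypothesis stays open. Each comparison of treated with saline mice was made within a day. At day 9, 2 of 17 clock genes rose in treated mice and 1 fell, Arntl. A different hour of killing between treated and saline mice was tested for day 3 only and remains untested at day 9.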
